A study of Arabidopsis thaliana with 4 samples.

How the data were processed

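Biotin-labelled cRNA made from 7 ug of total RNA per sample was hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are on a log2 scale, between 2.95 and 13.99, and RMA and limma are named in the submitters' processing notes without versions or settings. RMA corrects the background, quantile-normalises the arrays and summarises the probes of each probe set into a log2 value. Because it equalises the arrays, a change shared by all transcripts does not show in such values. Plants were grown at 22 degrees with 16 hours of light on medium with 0.8% agar, and low oxygen canisters were flushed for 20 minutes, per the labels' protocols.

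The table held 22810 probe sets, of which 64 controls were left out of the tests. Genes were named from the platform's probe table, and its symbols were updated by gene identifier through the RefSeq gene table of assembly TAIR10.1. Of the probe sets tested, 13513 had 1 gene, 503 had several and 8730 were not listed, and no gene was named for the last 2 kinds. Of the 1-gene probe sets, 13436 matched the RefSeq table and 77 did not. They covered 13355 genes, 11820 of which carry only a locus code as their name. Genome coordinates were not used here, since the sources used here name no genome build for the arrays.

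Differences between low and normal oxygen were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, 2-sided), with 2 arrays per group, no block and Benjamini-Hochberg adjustment over the 22746 probe sets. The fit had 2 residual degrees of freedom and 4.63 prior degrees of freedom, and the typical SD between replicates was 0.112 on the log2 scale. SEs of the log2 changes of single genes come from this fit. Replicates are separate pools of seedlings per the labels. Replicate numbers are shared by the groups, but no label says that they pair the samples.

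Gene lists were tested with limma's camera, with a preset correlation of 0.01 between genes, on 1 probe set per gene (the highest mean over all arrays), for lists with at least 3 measured members. The estimated-correlation form of camera and fry were run beside it. The former rests on the 2 residual degrees of freedom, so it has little power to call a list. Fry does not compare a list with other genes. Before the data were examined, 26 lists with 406 genes were fixed from textbook knowledge of root responses to low oxygen and of root and shoot cell types. Of those genes, 69 had a named probe set, and 6 lists could be tested. Of the other 20 lists, 13 had 1 or 2 measured members and 7 had none. A planned list of ribosomal proteins was not used here, since the tables give no gene titles. After the probe table was seen and before any test, 47 lists were added: plastid-encoded genes, mitochondrial-encoded genes and 45 families of at least 5 genes that share the letters of their symbol. A list of nuclear photosynthesis genes was added after the largest changes were seen and adjusted together with these, 48 lists in all. Class III peroxidases were listed after the largest falls were seen.

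Named genes were chosen by a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among 1-gene probe sets past the threshold, with groups that did not overlap and a mean of at least 6 in the higher group. It added up to 3 members per direction of each list, or 2 members as values where none passed, and 14 genes to be named in any case. Of those 14, 12 had no named probe set, among them the alcohol dehydrogenase and sucrose synthase genes, and were not analysed here. Further list members, and expansin genes outside the list, are named as examples chosen after their values were seen.

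Alternatives changed the prior (trend and robust), the normalization (quantile again, or median centring), the replicate block, a minimum level, the threshold, the treatment of several probe sets per gene and the arrays used. An alternative for linear values did not apply. The tests were tested on simulated data with the real means and with variances drawn from the fitted prior, in which 200 probe sets were changed. At log2 changes of 0.5, 1, 2 and 3, 8.0%, 88.0%, 96.0% and 100.0% of them were recovered, with 7 false calls among 153. Recovery depends on the share of probe sets changed, and 33.4% passed in the data, so these shares do not carry over to it. A list shifted by 1 was recovered by camera, and 0 of 54 unshifted lists were called. Genes were simulated independently, so this does not test the effect of correlation between genes.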

Results

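Transcript levels were measured in roots of 3-week-old Arabidopsis thaliana seedlings of the laboratory accession Col-0 on 4 one-colour Affymetrix expression arrays. There were 2 groups of 2 biological replicates, and each replicate was a pool of 5 seedlings from a shared dish. All seedlings were moved from agar to liquid medium with 3% sucrose for 24 hours and were then kept in foil-covered canisters for 5 hours. In the low oxygen group the canisters were flushed with gas containing 0.1% oxygen and sealed. In the normal oxygen group they were neither flushed nor sealed. Roots were cut off after the treatment. The values were log2 RMA expression values for 22746 probe sets, with array medians between 6.33 and 6.36, and the number of arrays limited the precision of every comparison.

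The design asked which root transcripts differed between 5 hours at low oxygen and 5 hours at normal oxygen. Among probe sets with a named gene, the largest rise was that of AT5G10040, a small protein gene known to be induced by hypoxia, which stood at 5.19 ± 0.68 (SD, n = 2) at normal oxygen and at 12.57 ± 0.37 at low oxygen (log2 change 7.39, SE 0.31, adjusted p = 1.7e-05). AT2G41730 rose by 7.17 (SE 0.10), from 5.28 ± 0.10 to 12.45 ± 0.03 (adjusted p = 1.8e-06). AT5G51440, which encodes a mitochondrial small heat shock protein, rose by 6.30 on the log2 scale (SE 0.10, adjusted p = 1.8e-06). WRKY22, a transcription factor gene of immune signalling, rose by 5.95 (SE 0.11), from 4.38 ± 0.04 to 10.33 ± 0.14 (adjusted p = 2.9e-06).

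The other 8 of the 12 largest rises lay between log2 changes of 4.99 and 5.70. They included AT3G54520 (5.70), AT5G48430 (5.56), AT5G43450 (5.45), which encodes a 2-oxoglutarate-dependent dioxygenase, and AT2G17850 (5.42), a rhodanese-domain gene. AT4G33666 rose by 5.38 and CML38, a calmodulin-like calcium sensor gene, by 5.37. CML38 had the widest spread of the 12 at normal oxygen, with a level of 6.05 ± 1.13 (SD, n = 2), against 11.43 ± 0.20 at low oxygen (adjusted p = 2.1e-04). ASPGB1, which encodes an asparaginase, rose 32.6-fold from a level of 7.17 ± 0.08, the highest normal oxygen level among the 12. AT1G54050, a further small heat shock protein gene, rose by 4.99. At normal oxygen, 10 of the 12, all but CML38 and ASPGB1, stood below 6, where signal over background is limited and RMA values carry no detection call, so their changes are differences of RMA values and no folds are given. AT3G54520 stood lowest there, at 3.61, close to the 5S ribosomal RNA control at 3.48.

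Among probe sets with a named gene, the largest fall was that of AT1G34510, a class III peroxidase gene, from 11.77 ± 0.02 to 6.81 ± 0.65 (SD, n = 2), a 31.0-fold difference (log2 change -4.96, SE 0.27, adjusted p = 3.9e-05). AT1G19900, a glyoxal oxidase-related gene, fell by 4.50 on the log2 scale (SE 0.10, adjusted p = 3.2e-06). XTH26, which encodes a xyloglucan-modifying cell wall enzyme, fell by 4.37 (SE 0.28), from 10.31 ± 0.10 to 5.95 ± 0.68 (adjusted p = 7.0e-05). The root hair expansin gene EXPA18 fell 11.6-fold and the endoglucanase gene GH9C1 fell 12.9-fold. The dirigent-like genes AT4G11210 and AT4G11190 had log2 changes of -3.84 and -3.15, and a further class III peroxidase gene, AT1G30870, had a change of -3.31 from a level of 12.09 ± 0.18. The remaining genes among the 12 largest falls were AT3G01260 (-4.01), AT4G33730 (-3.89), AT4G29700 (-3.71) and AT1G03820 (-3.35). At low oxygen 6 of the 12 stood below 6, with AT1G03820 lowest at 5.03.

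**Figure D1:**
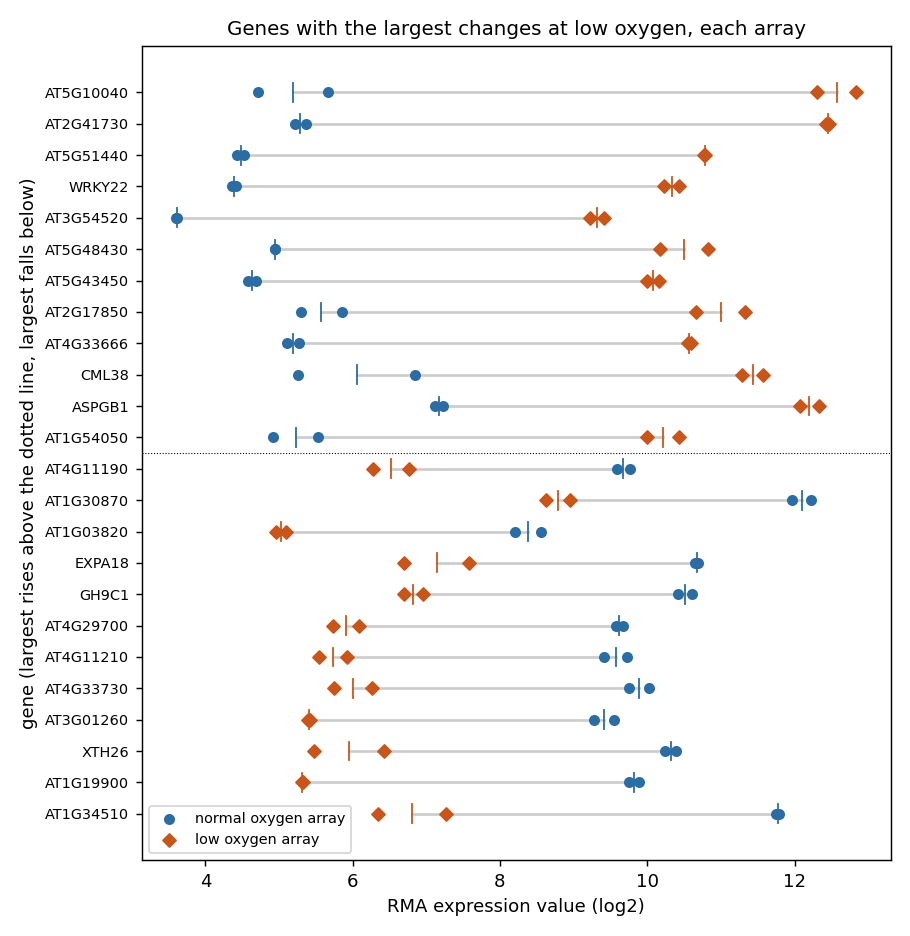
Log2 RMA expression value (horizontal axis) of the 12 named genes with the largest rises and the 12 with the largest falls (vertical axis), with circles for the normal oxygen arrays, diamonds for the low oxygen arrays and short vertical bars for the means of 2 arrays. Genes were chosen among those with groups that did not overlap, and their log2 changes ran from 7.39 for AT5G10040 at the top to -4.96 for AT1G34510 at the bottom.

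Among genes that roots are known to induce under hypoxia, 22 of the 44 on the list were measured by name, and 21 of these 22 rose. The same 21 passed when adjusted over the list alone. Besides AT5G10040, AT2G17850 and CML38, the larger changes included AT4G24110 (4.25, SE 0.36), AT3G10020 (3.52, SE 0.20) and AT5G42200 (3.37, SE 0.16). AT4G27450, already at 10.80 at normal oxygen, stood at 13.32 at low oxygen, and AT1G19530 went from 11.50 to 13.12. AT5G45960 was low in both groups, at 4.27 and 4.10 (adjusted p = 0.3197). Normal oxygen replicates 1 and 2 differed for some members, at 4.71 and 5.67 for AT5G10040 and 5.26 and 6.85 for CML38. Replicate 2 was also the higher for AT2G17850 (5.30 and 5.85), AT3G10040 (7.09 and 7.95) and AT3G03270 (9.15 and 9.54). The other members were not compared by array. The list's mean log2 change was 3.09, and it ran from 2.80 to 3.38 without each array in turn. The list passed limma's camera with its preset correlation (adjusted p = 2.1e-16). It did not pass with an estimated correlation (adjusted p = 0.2151), the highest value in a range over 12 alternatives that started at 3.0e-25.

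Of the fermentation genes, 3 of 9 were measured by name and 2 rose, both also when adjusted over the list alone. PDC2, a pyruvate decarboxylase gene of the ethanol pathway, rose 5.8-fold, from 9.55 ± 0.27 to 12.08 ± 0.04 (SD, n = 2, adjusted p = 4.1e-05). AT4G17260, which encodes lactate dehydrogenase, rose 5.3-fold, from 8.78 ± 0.03 to 11.19 ± 0.14 (adjusted p = 1.9e-05). ACS, the acetyl-CoA synthetase gene, was at 10.36 and 10.20 (adjusted p = 0.3243). The list's mean log2 change was 1.59 (camera adjusted p = 0.0331). The alternatives that ended the call included an estimated correlation (adjusted p = 0.2204), ranks (0.1653) and a filter for a mean of at least 6 in the higher group (0.0562), in a range over 12 alternatives from 4.8e-04 to 0.2204.

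The glycolysis genes measured by name did not move together. Of the 32 genes on the sucrose cleavage and glycolysis list, 7 were measured by name, none of them a sucrose cleavage gene. Of these 7, 2 rose, both also when adjusted over the list alone, and 5 did not pass. PPDK, which encodes pyruvate, phosphate dikinase, rose by 2.32 (SE 0.13), from 5.98 ± 0.20 to 8.30 ± 0.12 (SD, n = 2, adjusted p = 4.3e-05). The pyruvate kinase gene AT5G63680 rose by 0.45 (SE 0.10, adjusted p = 0.0124), a call that ended without low oxygen replicate 1 (0.40, adjusted p = 0.0766, the highest over 9 alternatives that began at 0.0093). The abundant GAPC2 transcript, of the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, was at 13.35 and 13.43 (adjusted p = 0.6585), and that of TPI, triosephosphate isomerase, differed by less than its SE of 0.10 (adjusted p = 0.9918). The list's mean change of 0.37 did not pass camera (adjusted p = 0.2770), and fry, which asks only whether the members move one way on balance, gave an adjusted p of 0.0237. Over 12 alternatives the adjusted p ran from 0.0237 to 0.4755.

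Tricarboxylic acid cycle genes differed little between the groups. Of the 11 of 24 measured by name, 1 fell and 10 did not pass, and none passed when adjusted over the list alone. SDH2-2, a succinate dehydrogenase subunit gene, fell by 0.41 (SE 0.11, adjusted p = 0.0264). The alternatives that ended that call included leaving out normal oxygen replicate 2 (-0.32, adjusted p = 0.1199), low oxygen replicate 1 (-0.45, adjusted p = 0.0822) and low oxygen replicate 2 (-0.37, adjusted p = 0.1321), and its adjusted p over 9 alternatives began at 0.0144. IDH-V, an isocitrate dehydrogenase subunit gene, had a change of -0.32 (SE 0.12, adjusted p = 0.0874). The list's mean change of -0.15 did not pass camera (adjusted p = 0.1609), and it ran from -0.21 without low oxygen replicate 1 to -0.09 without low oxygen replicate 2.

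Heat shock genes rose in all 4 members measured by name of the 19 on the list, also when adjusted over the list alone. All encode small heat shock proteins. Besides AT5G51440, AT1G53540 rose by 4.92 (SE 0.16), from 4.76 ± 0.05 to 9.68 ± 0.33 (SD, n = 2, adjusted p = 7.0e-06). AT5G37670 rose by 3.92 (SE 0.14) and ATHSP22.0, of the endoplasmic reticulum, by 2.99 (SE 0.10). The list's mean change was 4.53 (camera adjusted p = 9.2e-07), and the adjusted p was 0.1068 with an estimated correlation, the highest of 12 alternatives that began at 1.3e-07.

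Of the expansin genes on the list, whose products loosen growing cell walls, 9 were measured by name and 8 of these fell, also when adjusted over the list alone. No primary-wall cellulose synthase gene of the same list of 20 was measured by name. After EXPA18, the largest falls were those of EXPA7, a root hair gene, from 9.86 ± 0.30 to 7.36 ± 0.02 (SD, n = 2, adjusted p = 5.1e-05), and EXPA4, from 10.58 ± 0.04 to 8.68 ± 0.20 (adjusted p = 6.8e-05). EXPA20 was at 6.24 and 6.16 (adjusted p = 0.6925). Outside the list, EXPB2 fell by 1.13 (adjusted p = 0.0097), while EXPA16, EXPA21, EXPA24 and EXPB5 had changes of -0.24, 0.02, -0.12 and -0.13 (adjusted p = 0.0994, 0.9409, 0.4260 and 0.4017). Of the expansin-like genes, EXLA1 and EXLA2 fell by 0.82 and 0.44 (adjusted p = 0.0014 and 0.0219), EXLA3 rose by 1.34 (adjusted p = 2.6e-04), and EXLB1 had a change of 0.08 (adjusted p = 0.5986). The list's mean change was -1.61 (camera adjusted p = 1.4e-06), and the adjusted p was 0.1068 with an estimated correlation, the highest of 12 alternatives that began at 1.5e-07.

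**Figure D2:**
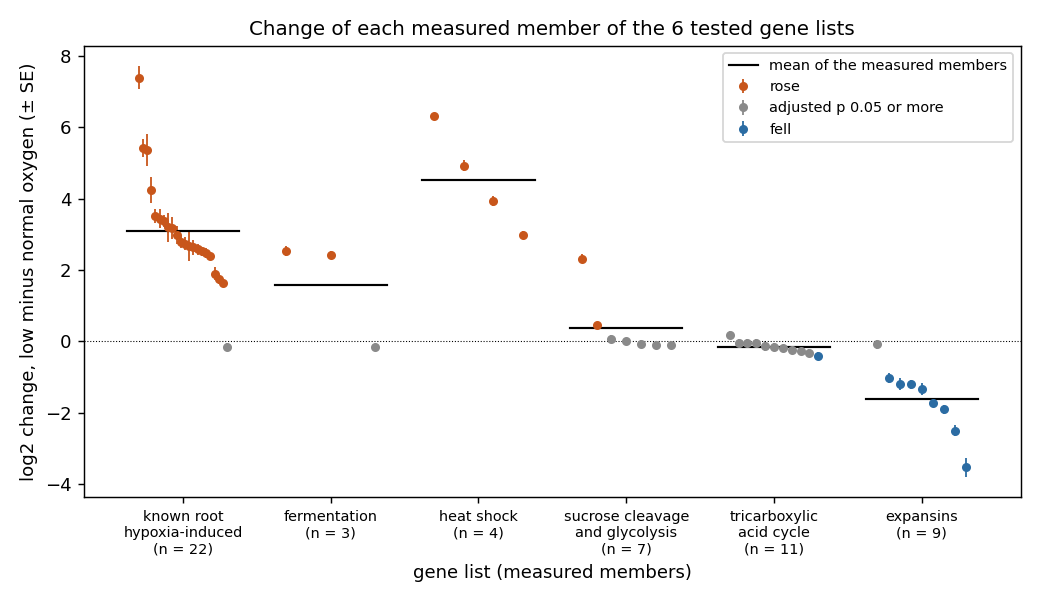
Log2 change at low oxygen (vertical axis, low minus normal oxygen, each point a gene with its SE) of the measured members of the 6 tested gene lists (horizontal axis, n is the number of members), with horizontal bars for list means. Means ran from 4.53 for heat shock genes to -1.61 for expansins, and glycolysis (0.37) and tricarboxylic acid cycle genes (-0.15) lay nearest 0.

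A further 13 lists had only 1 or 2 members measured by name and were not tested as lists. In the oxygen-sensing list both measured genes rose: AT3G10040, which encodes a trihelix factor that restrains the hypoxia response, 10.9-fold from 7.52 ± 0.61 (SD, n = 2, adjusted p = 1.3e-04), and AT3G03270, a universal stress protein gene, 6.9-fold from 9.34 ± 0.28 (adjusted p = 4.7e-05). AKINBETA1, a regulatory subunit gene of the energy-sensing kinase SnRK1, rose 3.0-fold (adjusted p = 2.3e-04). The vacuolar invertase gene AT1G62660 had a log2 change of -1.20 (adjusted p = 7.3e-04), HCT of lignin synthesis a change of -1.41 (adjusted p = 2.8e-04) and WRKY53, among touch and wound genes, a change of -1.28 (adjusted p = 0.0012). RTE1, a regulator of ethylene receptors, fell by 0.51 (adjusted p = 0.0070), while EIN3, the ethylene transcription factor gene, had a change of 0.31 (adjusted p = 0.0660). BHLH101, an iron-deficiency transcription factor gene, was low in both groups, at 3.98 and 4.67 (adjusted p = 0.0034). NDB2, an alternative NADH dehydrogenase gene, was at 10.04 and 10.00 (adjusted p = 0.7992).

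STZ, a zinc finger factor gene of oxidative stress, rose by 0.90 (SE 0.20, adjusted p = 0.0141), and the clock gene GI by 0.76 (SE 0.16, adjusted p = 0.0112). Both calls ended without low oxygen replicate 1 (STZ 0.90, adjusted p = 0.0800, and GI 0.74, adjusted p = 0.0717) and without low oxygen replicate 2 (STZ 0.89, adjusted p = 0.0835, and GI 0.77, adjusted p = 0.0648). Over 9 alternatives their adjusted p began at 2.4e-04 and 7.1e-04. PRL, a DNA replication licensing gene, was at 7.08 and 7.13 (adjusted p = 0.8358), and the dehydrin gene COR47 at 12.41 and 12.43 (adjusted p = 0.9403). Among the shoot markers only RCA, the Rubisco activase gene, was measured by name, and it rose from 6.95 ± 0.22 to 8.26 ± 0.16 (SD, n = 2, adjusted p = 5.9e-04) in these root samples. None of the listed markers of endodermis, vascular tissue or epidermis was measured by name, and none of the listed aquaporin, nitrogen assimilation, alanine and GABA, or sterol genes.

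Over all probe sets, 3594 were higher and 3999 lower at low oxygen in limma's test with Benjamini-Hochberg adjustment at 0.05, together 7593 or 33.4% of those tested. Of these, 1174 were at least 2-fold higher and 1211 at least 2-fold lower. The groups did not overlap for 64.5% of probe sets, against the 33.3% that chance gives for 2 against 2. Probe sets with a named gene made up 13513 of those tested, and 30.5% of them passed, as did 25.8% of the 503 with several genes and 38.2% of the 8730 not listed in the probe table. Of the 50 largest changes, 21 belonged to probe sets of the last 2 kinds, for which no gene was named. The control probe set for 25S ribosomal RNA also rose, from 6.90 ± 0.51 to 12.84 ± 0.14 (SD, n = 2, adjusted p = 1.1e-05). Flushing and sealing accompanied low oxygen in both of its replicates, so their effects were not separated from that of oxygen.

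Replicate arrays resembled each other more than arrays of different groups did. Across probe sets, which are not independent replicates, Pearson's r was 0.9958 between the normal oxygen arrays and 0.9962 between the low oxygen arrays, and it lay between 0.9446 and 0.9489 for pairs across groups. The SD of the log2 difference was 0.205 and 0.195 within the groups and 0.717 to 0.744 between them.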

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

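All tests in this part were chosen after the result was seen. The control probe set for cytosolic 25S ribosomal RNA, which lies outside the gene comparison, stood above its normal oxygen level on both low oxygen arrays. Its values were 6.54 and 7.26 on the normal oxygen arrays and 12.94 and 12.74 on the low oxygen arrays, a log2 change of 5.94 (SE 0.22, limma adjusted p = 1.1e-05). The 5S ribosomal RNA control was near the floor in both groups, at 3.48 and 3.48.

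Degraded messenger RNA in the low oxygen samples would lower signal from the 5' ends of transcripts. The mean 5' minus 3' difference over 6 control pairs of actin, GAPDH and ubiquitin changed by -0.10 (SE over the pairs 0.06). This was short of the fall of 0.5 set for it, a mark chosen only after the ribosomal result was seen. The pairs were read on the same arrays, so this SE is not an error over samples. The change was below 0 in 4 of the 6 pairs, at -0.24 and -0.23 for actin and -0.23 and -0.07 for ubiquitin, and was 0.13 and 0.01 for GAPDH. The 45 bacterial and phage spike-in probe sets rose by a median of 0.20 (SD 0.13), and 43 of the 45 were higher. Many of them read parts of the same transcripts on the same arrays, so this SD is not over independent controls. Their median was far below the rise of the ribosomal control, which the spike-ins thus did not share. RMA equalises the arrays, so these values cannot test brighter hybridisation of whole low oxygen arrays. A larger amount of ribosomal RNA entering the labelling step, tailing of ribosomal RNA, and binding of another induced transcript to these probes were not tested. An effect of the low oxygen treatment on ribosomal RNA also stays open, as untested.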

How the results depend on the processing

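The 7593 probe sets past the threshold (3594 higher, 3999 lower) became 2385 (1174 higher, 1211 lower) with a fold of at least 2 as well and 2303 (1149 higher, 1154 lower) when tested against a fold of 1.5. At an adjusted p under 0.01 there were 5062 (2361 higher, 2701 lower). Of the 7593, 1939 higher and 2186 lower were among the 13513 probe sets of 1 gene. Over these alone there were 4087 (1909 higher, 2178 lower) with 1 probe set per gene and 4098 (1919 higher, 2179 lower) with the mean of a gene's probe sets, so most of the drop came from leaving out the other probe sets. Without each array in turn the count ran from 5375 to 7001, with the lone array of a group assumed to vary like the other group. The other alternatives gave 6668 to 7766 calls. No main call changed sign under either normalization. None did without any single array, but calls past the threshold exceed the replicate spread, so this was nearly sure beforehand. The other prior and the replicate block leave the log2 changes as they are, so no sign could change under them. With the replicate block, 6939 probe sets passed and 6776 of them were main calls in the same direction. The numbers share no stated source, and the deviations of replicate 1 from 2 correlated at 0.024 between the groups. With the block 3 of the 4 list calls passed, fermentation had an adjusted p of 0.0672, and SDH2-2 had 0.0534. An estimated correlation rests on 2 residual degrees of freedom, which leaves little power, and 0 of the 48 added lists passed with it. The 4 list calls became 0 with it, and whether this low power or correlation between genes ended them was not tested. They stayed at 4 without any single array and after either normalization, and were 3 on ranks, 3 at a mean of at least 6 and 5 with fry. Of 46 named genes under 9 alternatives each, 42 kept their side of the threshold, and AT5G63680, SDH2-2, STZ and GI lost the call in 9 of 414 comparisons. None reversed. Signal over background limits dim genes: 45.6% to 46.2% of probe sets lay below 6 on each array.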

Other observations

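None of the lists in this part was fixed before the data were examined. The class III peroxidases, the nuclear photosynthesis list and the spike-in comparison were chosen after related values were seen. All 5 measured CSLC genes, which encode synthases of the xyloglucan backbone, fell, with CSLC5 at -1.51 (SE 0.15) and CSLC12 at -1.28 (SE 0.10). Of 22 TBL genes, a family of wall polysaccharide acetyltransferases, 13 fell and 9 did not pass, and TBL28 changed most (-1.68, SE 0.11). The 6 EXPA genes that fell of 10 are also on the expansin list. Symbols with GH cover both the GH9 endoglucanases and the GH3 auxin-conjugating enzymes, and of these 19 genes 9 fell and 1 rose. GH9C2 had a change of -2.34 (SE 0.13), whereas GH3.3 rose from 4.77 ± 0.11 to 9.62 ± 0.10 (SD, n = 2), the only rise. Of 29 SCPL genes, of serine carboxypeptidase-like proteins, 12 fell, led by scpl40 (-1.98), and of 11 PRA genes, of prenylated Rab acceptors, 6 fell, led by PRA1.B6 (-1.44).

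Of the 48 added lists, 9 passed limma's camera. Adjusted p was 9.2e-04 for the CSLC, EXPA and SCPL genes, 1.4e-04 for TBL, 0.0125 for GH and 0.0082 for PRA, with mean log2 changes of -1.11, -1.25, -0.44, -0.62, -0.39 and -0.55 in that order. With an estimated correlation, a form with little power at 2 residual degrees of freedom, all 6 had an adjusted p of 0.7668. None of the 6 calls held in that form, and PRA had 0.0598 with fry. Over genes with a mean of at least 6 in the higher group, the means were -0.73 for GH (adjusted p = 0.0474) and -0.74 for SCPL (0.0023). The 9 XTH genes, of xyloglucan-modifying enzymes, included 5 that fell and 1 that rose, and the family did not pass camera (adjusted p = 0.1040). None of these 6 families turned direction under any of 12 alternatives, whose lowest adjusted p lay between 6.8e-05 (TBL) and 0.0115 (GH).

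The lists of mitochondrial and plastid transcripts had means of opposite sign, and the difference between them was not tested. Of 16 genes with mitochondrial names, 8 rose and 8 did not pass. Those that rose included nad5 (1.39, SE 0.15) and nad1 (1.37, SE 0.14), both of subunits of respiratory complex I. Both were dim, nad5 going from 4.80 to 6.19 and nad1 from 5.10 to 6.47. The list's mean was 0.51 (camera adjusted p = 0.0071). The mitochondrial call ended with an estimated correlation (adjusted p = 0.7668) and at a mean of at least 6 (0.0682), in a range over 12 alternatives from 9.7e-04. On the same arrays the 25S ribosomal RNA control rose by 5.94 and the spike-ins had a median change of 0.20. Of 69 plastid-encoded genes, 14 fell, 2 rose and 53 did not pass. The gene for the large Rubisco subunit, rbcL, fell from 8.73 ± 0.05 to 7.18 ± 0.23 (SD, n = 2), while psbF rose by 0.71 (SE 0.22). The plastid mean was -0.27 (adjusted p = 0.0125), but it was -0.07 (0.5323) without normal oxygen replicate 2 and -0.20 (0.2155) without low oxygen replicate 1, against -0.47 (1.5e-06) without normal oxygen replicate 1 and -0.35 (0.0033) without low oxygen replicate 2. The adjusted p was 0.9590 with an estimated correlation and 0.3707 with fry. It also missed the threshold at a mean of at least 6 (0.0789), in a range from 1.5e-06 to 0.9590.

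A different share of leaf tissue in the root samples would move plastid and nuclear photosynthesis transcripts the same way. The plastid median was -0.28, whereas the 9 nuclear photosynthesis genes measured, of 44 listed, had a median of 0.55 (SE of their mean 0.13). Of these 9, 7 rose, among them RCA (1.31) and LHCB4.1 (0.76, SE 0.13). Leaf tissue alone would thus not account for both shifts if the plastid fall is not chance. Whether more leaf tissue accounts for the nuclear rise alone was not tested. In normal oxygen roots too, 7 of the 9 stood at 6 or above, LHCB4.1 the highest at 8.21. The spike-ins had a median of 0.20 (SD 0.13 over probe sets that are not independent), in the direction opposite to the plastid transcripts. RMA equalises the arrays, so these values cannot test a difference in hybridisation or scaling of whole arrays. The nuclear list passed camera (adjusted p = 0.0065) but had 0.8931 with an estimated correlation and 0.0726 with fry, the range starting at 0.0022. An effect of low oxygen on plastid transcripts stays open, as does chance, since leaving out either of 2 arrays ended the call.

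Class III peroxidases, enzymes of the cell wall, were looked at because 2 of the 12 largest falls belonged to them. Of 55 measured by name of 74 listed, 29 fell, 7 rose and 19 did not pass. AT5G39580 rose by 4.72 (SE 0.11) and AT1G14550 by 3.43 (SE 0.15), so the family did not move as a whole. The median change was -0.38 (camera p = 1.3e-05, and p = 0.0326 with an estimated correlation, the highest of 12 alternatives that began at 4.0e-07). If only the strongly expressed root genes fell, random lists matched on normal oxygen level would fall as far, but 100% of 10000 such lists had a higher median, and the median of their medians was -0.05. Random genes were drawn without regard to family, and genes of a family can move together, so the random medians may vary too little. The 2 peroxidase genes that prompted the list were also kept in it. A lower level of many peroxidase transcripts at low oxygen, beyond a feature of their normal oxygen levels, is thus only a hypothesis. This hypothesis was noticed and tested on the same arrays, and a fall shared with other root genes stays open.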
